A study of Mus musculus with 17 samples.

How the data were processed

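The assay was Tri-C, a chromosome conformation capture method: cross-linked chromatin is digested with the restriction enzyme NlaIII, ligated, and enriched with oligonucleotides for a chosen fragment, the viewpoint. A read that joins the viewpoint to at least a pair of other fragments reports a three-way contact on a single allele. Per the labels, 10 libraries came from primary erythroid cells and 7 from mouse ES cells. The erythroid cells were selected by the surface marker Ter-119 from spleens of C57BL/6 mice made anaemic with phenylhydrazine. The libraries are technical replicates of 3 biological replicates per cell type, and the technical replicates of each were summed, so that n = 3 in each group. The labels do not say whether a biological replicate is one animal or one culture. If the replicates are not from separate animals or cultures, the p-values measure only the spread between these samples. The ES cells are the E14 line, and per the labels both cell types also differ in mouse strain, so cell type and strain cannot be told apart in any comparison here.

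The deposited values are whole-number counts, as the files show: each entry of the authors' 4 tables, one per viewpoint, is a pair of NlaIII fragments with its count in each of the 17 libraries. The tools Trim Galore and Bowtie and the genome build mm9 are named in the submitters' processing notes, with no version, role or order. How duplicates were removed, how reads were filtered and how fragments were called is not given in the sources used here. All coordinates below are mm9 and 1-based. The gene table used here is of assembly GRCm38.p6, so it served for names only, and no mm9 annotation was used.

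Each viewpoint was located as the longest gap between the fragments of its table within a short stretch around its known place, since the viewpoint itself is not listed as a contact. The R2 gap was at chromosome 11, 32149923 to 32152111, and the alpha CTCF gap at chromosome 11, 32136092 to 32138888. The HS2 gap was at chromosome 7, 111008334 to 111011358, and the beta CTCF gap at chromosome 7, 110954158 to 110956820. Distances are from the centres of these gaps, positive towards higher coordinates. Fragments within 1 kb of the viewpoint were left out. Fragments that lie off the viewpoint chromosome follow the fragment boundaries of the viewpoint chromosome in every table: 0 of 332515 such fragments in the R2 table crossed one, against 130544 after the boundaries were shifted by 1 kb. Their coordinates on other chromosomes were therefore not read as positions, and only their share was used.

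Contacts were counted in 2 kb bins within 150 kb on either side of the viewpoint, each contact pair adding 1 to the bin of each of its fragments; bins with fewer than 50 counts over all replicates were left out. Three-way contacts were counted per pair of 4 kb bins, with a minimum of 30 counts. Levels are given as contacts, or contact pairs, per 1000 contact pairs of the whole table. Differences were tested with edgeR 4.0.16 (quasi-likelihood test, R 4.3.3), separately for each viewpoint, with the table's total count as library size, no normalization factors, and Benjamini-Hochberg adjusted p under 0.05 as threshold. The fold changes are log2 values, erythroid minus ES, with their standard error. In edgeR this error was not estimated directly. It is the size of the log2 change divided by the square root of the test's F statistic. DESeq2 1.42.0 with its own size factors was run beside it. Single shares were compared with exact two-sided permutation tests, for which 3 against 3 allows no p below 0.1. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

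Named elements were fixed before the data were examined, as were the tests and most alternatives. At the alpha locus they are 3 kb windows placed by the sites' usual names, which count kb from Hba-x. At the beta locus they are broader ranges, because individual genes were not annotated on mm9 here: the adult genes, the embryonic genes, the rest of the locus control region, and an upstream and a downstream flank. The downstream flank was meant to hold a CTCF site but does not contain the beta CTCF viewpoint, which lies at -54.4 kb from HS2. Pairs of elements were tested once for frequency and once against an expected count. The expected count of a pair of bins is the product of both bins' own contact frequencies and an effect of their separation, fitted per replicate by 200 rounds of iterative scaling on 2 kb bins. Besides the elements, the rule names up to 5 bins and 5 bin pairs per direction and viewpoint, those of largest change among calls in which all replicates of one group lie on one side of the other group. The contacts of single elements, and a window at the beta CTCF site seen from HS2, were added after the files had been examined.

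Reads without molecular identifiers are not independent molecules, so counts and floors cover counting error only. The tests were tested on simulated data with the real means, depths and spread, in 20 draws per comparison. Of bins changed 4-fold, 83.3% were recovered for R2, 100% for alpha CTCF, 20% for HS2 and 51% for beta CTCF; for 2-fold changes the shares were 31%, 74%, 2.50% and 5.33%. Of 4-fold changed bin pairs, 18.2% were recovered for R2, 17.1% for alpha CTCF, 0.903% for HS2 and 0.200% for beta CTCF. For element pairs changed 4-fold, the shares were 32.5%, 7.50%, 25% and 10% in the same order, and against the expected count 38.8%, 3.75%, 60% and 45%. In these draws the expected counts were kept fixed, whereas in the real data they are fitted to the same counts. The simulated results against the expected count, recovered or on unchanged pairs, therefore leave out what refitting absorbs or passes to other pairs. Calls also fell on unchanged features: against the expected count 4 of 43 for R2, 1 of 5 for alpha CTCF, 6 of 22 for HS2 and 0 of 10 for beta CTCF, and for element pairs 0 of 28, 0 of 6, 0 of 6 and 4 of 6. For bins these were 12 of 355, 16 of 538, 4 of 67 and 2 of 171, and for bin pairs 14 of 364, 7 of 371, 1 of 11 and 0 of 4. In a separate simulation from the counts of erythroid replicate 1, in which the expected count was refitted, it absorbed part of a raised pair. A pair raised by 1.58 on the log2 scale came back at a median of 1.27 for R2, 1.38 for alpha CTCF, 0.82 for HS2 and 1.20 for beta CTCF. Lowered pairs were not simulated, and departures of real pairs also depend on the other pairs in the fit.

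Total counts per library ranged from 57013 to 153422 for R2, 48803 to 136815 for alpha CTCF, 34968 to 146427 for HS2 and 44800 to 327659 for beta CTCF. The 3 erythroid first technical replicates stood apart from the other 14 libraries. An off-chromosome fragment pair of theirs was counted 1.30 to 1.36 times on average in the R2 table, against 3.00 to 3.80 in the others. Each result was therefore also computed with every fragment pair counted once per library and without these 3 libraries, both chosen after seeing the data. In the alternative with first technical replicates alone, these 3 libraries are the whole erythroid side. There, what sets them apart cannot be told from cell type. Other alternatives were TMM normalization factors, the total within the 150 kb window or on the viewpoint chromosome as library size, other bin sizes, count minimums and window widths, a wider exclusion at the viewpoint, the share within 100 kb among pairs on the viewpoint chromosome, a replicate block, the first technical replicates alone, an expected count without the separation effect, and each biological replicate left out in turn. The window and chromosome totals count only pairs with both fragments inside, whereas single elements and bins also count a fragment whose partner lies outside. For the expected count at the alpha locus, pairs that join both alpha-globin gene copies were also left out of its fit. This last alternative, the chromosome total, also as the base of that share, and DESeq2 with the table total or the expected count as size factor were likewise chosen after seeing the data.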

Results

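Three-way chromatin contacts were measured by Tri-C at the mouse alpha-globin and beta-globin loci, in primary Ter-119+ erythroid cells, where both loci are active, and in ES cells, where they are inactive. The question set by the design is which regulatory elements meet on a single allele in each state. There were 4 viewpoints. R2 is an enhancer of the alpha-globin genes, which with R1, R3, Rm and R4 forms their upstream enhancer cluster. The alpha CTCF viewpoint is a site of the insulator protein CTCF in the upstream flank of that cluster. HS2 is an enhancer of the beta-globin locus control region, and the beta CTCF viewpoint lies beyond the adult beta-globin genes on the side away from it.

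Each cell type had 3 biological replicates. Their total counts lay between 139337 and 469501 for R2, 129858 and 459669 for alpha CTCF, and 84849 and 464338 for HS2. For beta CTCF, ES replicates 2 and 3 held 93686 and 125570 counts against 785662 in ES replicate 1, and the erythroid replicates held 658673 to 1082506. From R2, 49.98% ± 7.16 of erythroid contact pairs had neither fragment on chromosome 11, against 18.3% ± 5.27 in ES cells (SD, n = 3; exact permutation p = 0.1, the smallest that 3 against 3 allows). From alpha CTCF in the same replicates the shares were 26.6% ± 6.45 and 28.7% ± 4.75 (n = 3, exact permutation p = 0.6). The share was 51.02% ± 9.48 against 32.7% ± 5.35 from HS2 (n = 3, exact permutation p = 0.1) and 47.9% ± 7.38 against 35.4% ± 10.5 from beta CTCF (n = 3, exact permutation p = 0.2). Changes below are relative to a table's total unless stated otherwise. These shares therefore bear on every level from R2, and likewise on those from HS2 and beta CTCF.

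**Figure D1:**
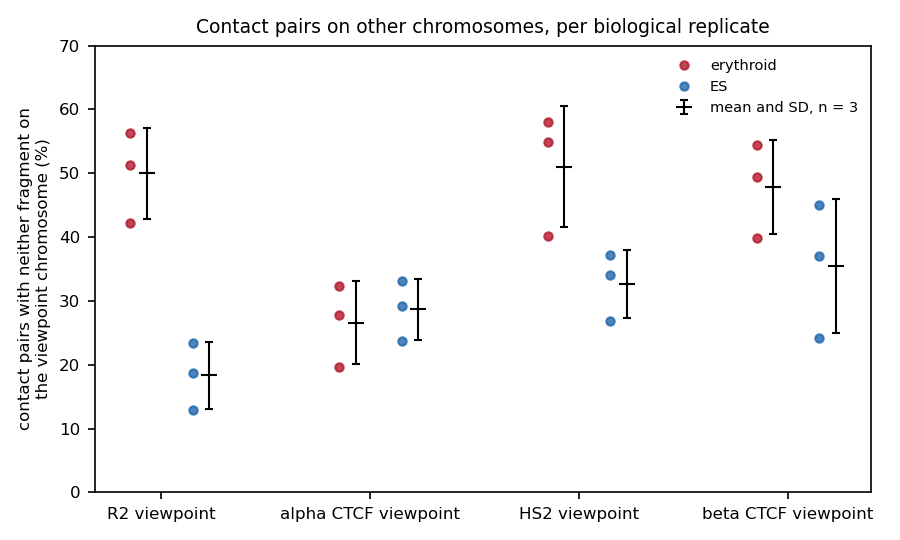
Share of contact pairs with neither fragment on the viewpoint chromosome (percent), for each viewpoint and biological replicate; points are replicates and bars the mean and SD of n = 3. From R2 the erythroid replicates lie at 42.2 to 56.4% and the ES replicates at 12.9 to 23.4%, while from alpha CTCF both groups lie between 19.6 and 33.2%.

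Seen from the R2 enhancer, contacts with the alpha-globin genes rose in erythroid cells while contacts with the flanks of the locus fell. Hba-a1 and Hba-a2, which encode the adult alpha-globin chains, were contacted 25.1 ± 5.67 and 23.9 ± 4.77 times per 1000 contact pairs in erythroid cells, against 13.6 ± 3.19 and 14.9 ± 3.58 in ES cells (SD, n = 3). These are log2 changes of 0.88 (SE 0.29) and 0.69 (SE 0.29), and of 1.95 and 1.76 relative to the 150 kb window. The CTCF pair at -38/-39, in the upstream flank, fell from 32.23 ± 4.39 to 10.8 ± 2.13, and the downstream CTCF sites +44 and +48 fell by 1.26 (SE 0.32) and 1.30 (SE 0.31) on the log2 scale. The call at +44 and +48 ended when scaled to the window, with log2 changes of -0.20 and -0.26, whereas that at -38/-39 stayed past the threshold at -0.54.

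Among the other members of the enhancer cluster, R3 fell by 1.07 (SE 0.25) on the log2 scale, but its change was -0.01 (SE 0.16) relative to the window and 0.03 relative to the chromosome total. R1 fell by 0.69 (SE 0.25) relative to the table total, but its direction turned to 0.42 (SE 0.15) relative to the window and 0.44 relative to the chromosome total. The window and chromosome totals hold only pairs with both fragments inside, while element counts also include fragments whose partner lies outside. What this difference adds to such turns was not tested. For Rm, a weaker element of the cluster, the change was -0.31 (SE 0.30), turning to 0.80 relative to the window and 0.23 in DESeq2, and for R4 it was 0.52 (SE 0.31) and 1.61. Hba-x, the embryonic zeta-globin gene, had a change of -0.08 (SE 0.31), turning to 0.96 relative to the window and 0.41 in DESeq2. In edgeR's quasi-likelihood test over these 10 elements, Hba-a1 (adjusted p = 0.00889) and Hba-a2 (adjusted p = 0.0339) rose and 5 elements fell. DESeq2 with its own size factors called 9. Without ES replicate 3 the count was 4 and neither gene passed the threshold, with adjusted p of 0.0593 at Hba-a1 and 0.164 at Hba-a2, against ranges over all 17 alternatives of 3.09e-29 to 0.0969 and 1.23e-24 to 0.164 (edgeR or DESeq2). The call at Hba-a1 was also lost without erythroid replicate 3 (0.68) or ES replicate 1 (0.77), that at Hba-a2 without every replicate but ES replicate 2 (0.51 to 0.78), and that at R1 without erythroid replicate 1 or 2 or ES replicate 2 or 3 (-0.76 to -0.42).

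Along the whole window around R2, 9 of 150 bins rose and 128 fell in erythroid cells (edgeR's quasi-likelihood test). The rising bins lay at +16 kb, at R4, and from +30 to +46 kb except +38, around Hba-a1 and Hba-a2. The largest rise, of 1.18 (SE 0.25, adjusted p = 0.000442), was at chromosome 11, 32187017 to 32189016, between both genes, where contacts went from 5.30 ± 0.47 to 12.0 ± 0.30 per 1000 contact pairs; the other 4 named rises, all around Hba-a1 or between the genes, were of 0.88 to 1.07. The bins named for the largest falls lay 74 to 150 kb from R2, and the one at 32297017 to 32299016 fell by 4.05 (SE 0.69). The named rise at +40 kb was lost without erythroid replicate 1 (0.78) or any ES replicate (0.69 to 1.03), and that at +32 kb without ES replicate 3 (0.78). The number of rising bins was 4 without ES replicate 3, 5 without ES replicate 1 and 6 without erythroid replicate 1. Replicate groups did not overlap in 90.7% of the bins, where chance gives 10% for each bin taken alone. Bins and bin pairs of one table share its total count and can move together. Such shares, here and below, therefore do not come from independent features. The balance of rises and falls depended on scaling: 21 bins rose and 100 fell relative to the window, 38 rose and 28 fell with TMM factors, and 44 rose and 22 fell with DESeq2. The median log2 change over all bins was -2.31 relative to the table total, -1.32 relative to the window, -1.25 relative to the chromosome total, -0.41 with TMM and -0.20 with DESeq2.

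**Figure D2:**
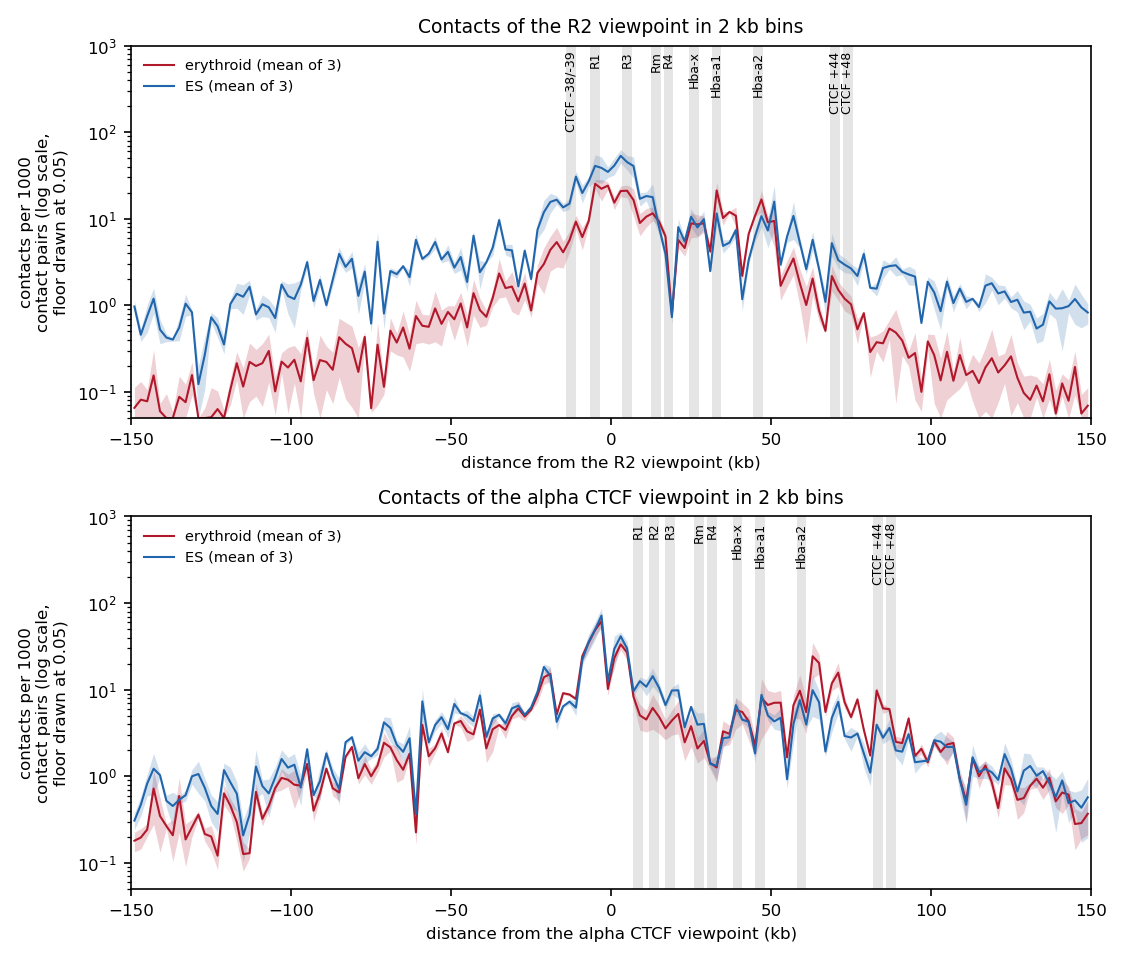
Contacts per 1000 contact pairs (log axis) in 2 kb bins against the distance in kb from R2 (top) and alpha CTCF (bottom); lines are means of 3 replicates, shading is the SD, and grey bands are the named elements. On this scale, relative to the table total, the erythroid line from R2 lies above the ES line at Hba-a1 and Hba-a2 and below it in both flanks and around R2; 128 bins fell over the window, while relative to the window 100 fell and with TMM factors 28.

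Three-way contacts of R2 with R1 and an alpha-globin gene rose. R1 is the neighbouring enhancer of the same cluster. R2 met R1 and Hba-a1 together in 0.58 ± 0.03 of 1000 contact pairs in erythroid cells and 0.16 ± 0.08 in ES cells, a log2 change of 1.83 (SE 0.39, adjusted p = 0.00154, edgeR). With Hba-a2 in place of Hba-a1 the values were 0.53 ± 0.08 and 0.15 ± 0.04, a change of 1.82 (SE 0.37, adjusted p = 0.00146, edgeR). Contacts of R2 that joined the upstream CTCF pair with R1 or with R3 fell by 1.30 (SE 0.35) and 2.19 (SE 0.40). The other 41 of 45 element pairs did not pass edgeR's threshold, among them the pairs of R1, R3, Rm and R4 with each other, while DESeq2 called 8 pairs. Rm with R4 had a change of 2.62 (adjusted p = 0.167, edgeR) and passed the threshold under some alternatives. Its adjusted p over all 17 was 0.00548 to 0.562 (edgeR or DESeq2). R4 with Hba-a1, R4 with Hba-a2 and R1 with Hba-x likewise passed under some, with lowest adjusted p of 0.00133, 0.00177 and 0.00961 (edgeR or DESeq2).

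The calls of R1 with Hba-a1 and with Hba-a2 were also made relative to the window, with log2 changes of 2.89 and 2.95, while the CTCF pair with R1 and with R3 missed the threshold there, at -0.22 and -1.12. With the first technical replicates alone only R1 with Hba-a1 passed the threshold, but on the erythroid side these are the libraries that stood apart. Without erythroid replicate 2 or ES replicate 2 the call of the CTCF pair with R1 was lost (-1.13 and -0.96). Without ES replicate 2 or 3 the count of calls was 8 or 7. The nearly identical gene copies set a further limit. In a comparison of the fragments of both copies, 8 fragments of equal length lay 12817 bp apart. Their counts differed by a median of 0.02 (ES) and 0.06 (erythroid) on the log2 scale. Those of 36 and 92 bp differed more, with erythroid counts of 1975 and 1105 and of 2809 and 2137. Their ES counts were 572 and 478 and 713 and 825. With medians this small, values of Hba-a1 and Hba-a2 are not independent, and no difference between both genes was tested.

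Against the expected count, R1 and Hba-a2 met at R2 more often in erythroid than in ES cells, by 1.58 on the log2 scale (SE 0.32, adjusted p = 0.000225, edgeR). Observed over expected was 0.84 in erythroid and -0.74 in ES cells on that scale, but 1.00 and 0.06 with each fragment pair counted once per library and 1.38 and -0.003 with pairs that join both gene copies left out of the fit, so the low ES value was not kept. For R1 and Hba-a1 the difference was 0.84 (SE 0.40, adjusted p = 0.457). Hba-a1 and Hba-a2 stood above their expected count in both cell types, by 1.59 in erythroid and 3.02 in ES cells, and the difference of -1.43 (SE 0.21) passed the threshold. In this last fit, both alternatives being chosen after seeing the data, the call for R1 and Hba-a2 was kept at 1.39 (SE 0.33) and that for Hba-a1 and Hba-a2, at 5.14 and 6.27, was lost at -1.13 (SE 0.46). In simulated data of this test, in which the expected counts were not refitted, 4 of 43 calls fell on unchanged pairs. The call for R1 and Hba-a2 was lost without erythroid replicate 1 (1.51) or 2 (1.47), each of which left 1 call, and with the first technical replicates alone.

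Within the erythroid cells alone, R3 with Rm (0.95) and R1 with Rm (0.68), all enhancers of the cluster, and R1 with Hba-x (0.80) also stood above the expected count on the log2 scale, with adjusted p of 0.000125, 0.0141 and 0.0298 in edgeR. With each fragment pair counted once these were 0.59, 0.33 and 0.49, and with gene copy pairs left out 0.74, 0.42 and 0.47. In ES cells R1 with R4, a weaker enhancer, stood at 1.13 (adjusted p = 0.0252, edgeR), a call lost with each fragment pair counted once (0.41, adjusted p = 0.72). R4 with Hba-a1 (-3.17, 8 counts) and Rm with Hba-a1 (-1.60) stood below the expected count in ES cells with the same adjusted p, and these calls were lost as well when counted once (-1.58 and -1.01, adjusted p = 0.237 and 0.191). R3 with Rm was at 0.50 in ES cells and R1 with Rm at 0.44, and neither pair's difference between the cell types passed the threshold. R1 with R3 was at 0.12 in erythroid and 0.07 in ES cells.

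**Figure D3:**
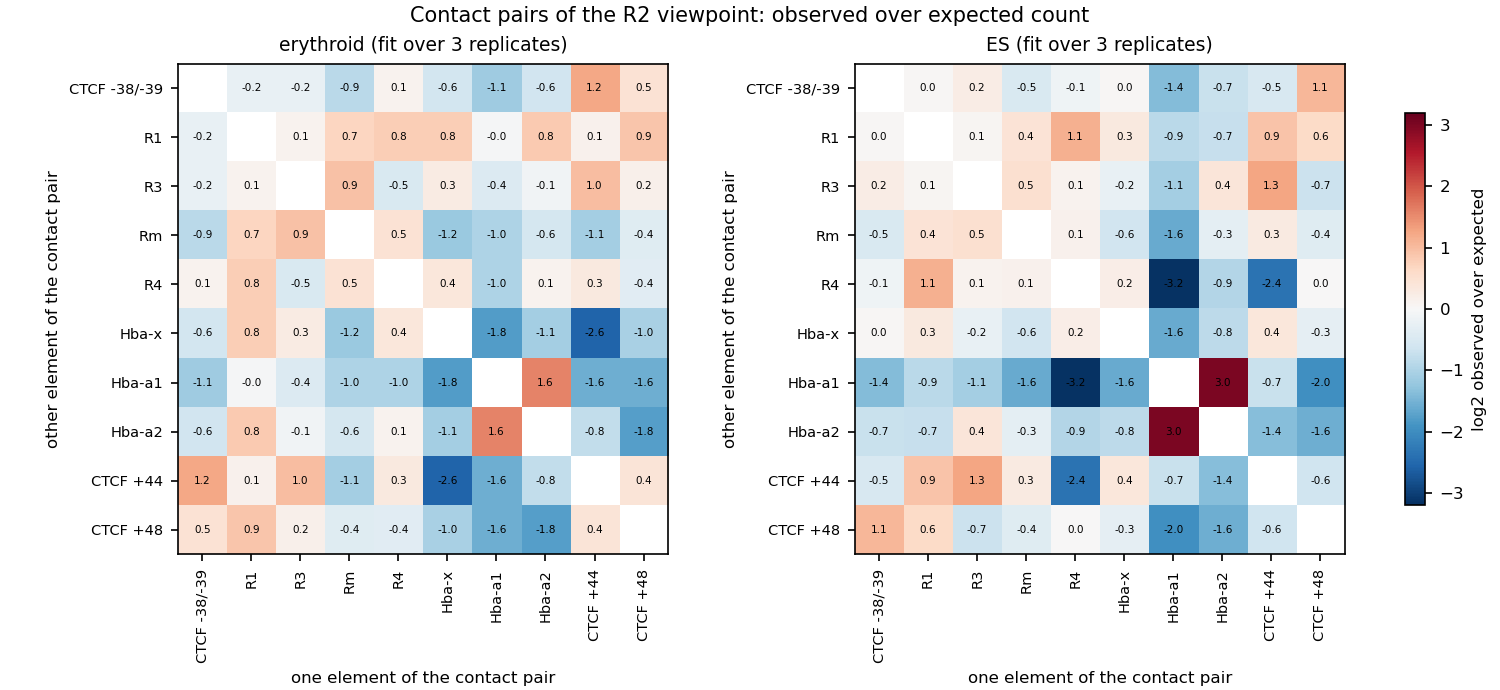
Log2 of observed over expected count for each pair of named elements contacted together with R2, in erythroid (left) and ES cells (right), from a fit over 3 replicates each. The pair of Hba-a1 and Hba-a2 is at 1.59 and 3.02, and R1 with Hba-a2 at 0.84 and -0.74; with pairs joining both gene copies left out of the fit, which is not drawn, these were 5.14 and 6.27, and 1.38 and -0.003.

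Over all pairs of 4 kb bins contacted with R2, 18 of 897 rose and 256 fell in erythroid cells (edgeR). All but 1 of the 5 named rises involved an alpha-globin gene. A bin at R4 was joined with Hba-a1 (3.11, SE 0.99) or Hba-a2 (2.48, SE 0.76). The bin beside R2, at -4 to 0 kb, was joined with Hba-a2 (2.50, SE 0.46) or Hba-a1 (2.18, SE 0.44). That bin only touches the R1 window, which lies at -6.5 to -3.5 kb. The exception joined a bin 44 kb upstream with the one at the CTCF site +44, with 47 counts in erythroid and 0 in ES cells, at least 12.0-fold higher by a floor of 3 counts over the group. The 5 named falls had 0 counts in erythroid cells and were at least 23.1 to 38.3-fold lower by the same floor. In ES libraries a fragment pair within 150 kb was counted 5.62 to 8.23 times on average. These folds and the 12.0-fold rise are therefore not bounds in molecules. No value with each fragment pair counted once was available for these falls or for that rise. The falls included pairs of far bins with a bin at Rm and with the bin beside R2, at 0 to 4 kb. The latter bin only touches the R3 window, at 3.5 to 6.5 kb. Groups did not overlap in 47.8% of bin pairs, where chance gives 10%. The balance of rises and falls moved with scaling, with 56 rises and 67 falls relative to the window, 85 and 22 with TMM, and 73 and 105 with DESeq2. Without ES replicate 1 the count fell to 120, without ES replicate 3 to 160, and without erythroid replicate 1 or 2 to 182 or 181, with 8, 10, 9 and 12 rises in this order. Among the named rises, R4 with Hba-a1 was lost without erythroid replicate 1 or 3 or ES replicate 2 or 3 (2.59 to 3.22), R4 with Hba-a2 without erythroid replicate 1 or ES replicate 1 or 3 (2.08 to 2.74), and the pair at CTCF +44 without erythroid replicate 1 or 2 or ES replicate 1 or 3 (adjusted p 0.0596 to 0.115 in edgeR, against 0.00098 to 0.121 over all its alternatives). The 27 ES counts of R4 with Hba-a1 lay in a single replicate, and over 16 alternatives its change was 2.59 to 8.89.

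The share of R2 contact pairs with both fragments within 100 kb of the enhancer was 16.4% ± 4.07 in erythroid and 32.3% ± 9.04 in ES cells (n = 3, exact two-sided permutation p = 0.1, the smallest possible here). All 3 erythroid replicates lay below all 3 ES replicates. Among pairs with both fragments on chromosome 11, an alternative chosen after seeing the data, the shares were 50.03% ± 0.795 and 46.4% ± 8.05 (n = 3, exact two-sided permutation p = 0.4), so the lower erythroid share was not kept. With each fragment pair counted once per library the difference went from -15.98 to -8.99 percentage points. In ES libraries, pairs within 150 kb were counted 5.62 to 8.23 times on average and off-chromosome pairs 3.00 to 3.26 times. Counting once therefore lowers the near share in ES cells by construction.

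Seen from the alpha CTCF site, contacts with the enhancers R1, R2 and R3 fell and contacts with CTCF sites on the far side of the gene cluster rose. The CTCF site +44, downstream of the genes, was contacted 13.5 ± 1.253 times per 1000 contact pairs in erythroid cells and 5.40 ± 0.67 times in ES cells (SD, n = 3), a log2 rise of 1.32 (SE 0.24, adjusted p = 0.00339, edgeR). CTCF +48 beside it rose by 0.63 (SE 0.22), from 4.94 ± 0.82 to 7.65 ± 0.31. The enhancers R1, R2 and R3 fell by 0.89 (SE 0.29), 1.15 (SE 0.37) and 1.04 (SE 0.28) on the log2 scale, R2 from 20.6 ± 4.74 to 9.25 ± 3.85.

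The other elements seen from alpha CTCF did not pass the threshold. The weaker enhancer elements Rm and R4 had changes of -0.78 (SE 0.32) and -0.08 (SE 0.17), the embryonic gene Hba-x of -0.04 (SE 0.30), and the adult genes Hba-a1 and Hba-a2 of -0.05 (SE 0.39) and 0.35 (SE 0.37); in DESeq2 R4, Hba-x and Hba-a1 turned to 0.23, 0.20 and 0.12. All 5 called elements kept their call relative to the 150 kb window and with DESeq2, which called 7. Only CTCF +44 passed without erythroid replicate 1 or without ES replicate 1, with R3, for example, at -0.97 and -1.03. The count was 3 without erythroid replicate 2 (R2, R3 and CTCF +44) and 2 without ES replicate 2 (both CTCF sites); without ES replicate 3 the calls at R1 (-0.96) and CTCF +48 (0.58) were lost.

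**Figure D4:**
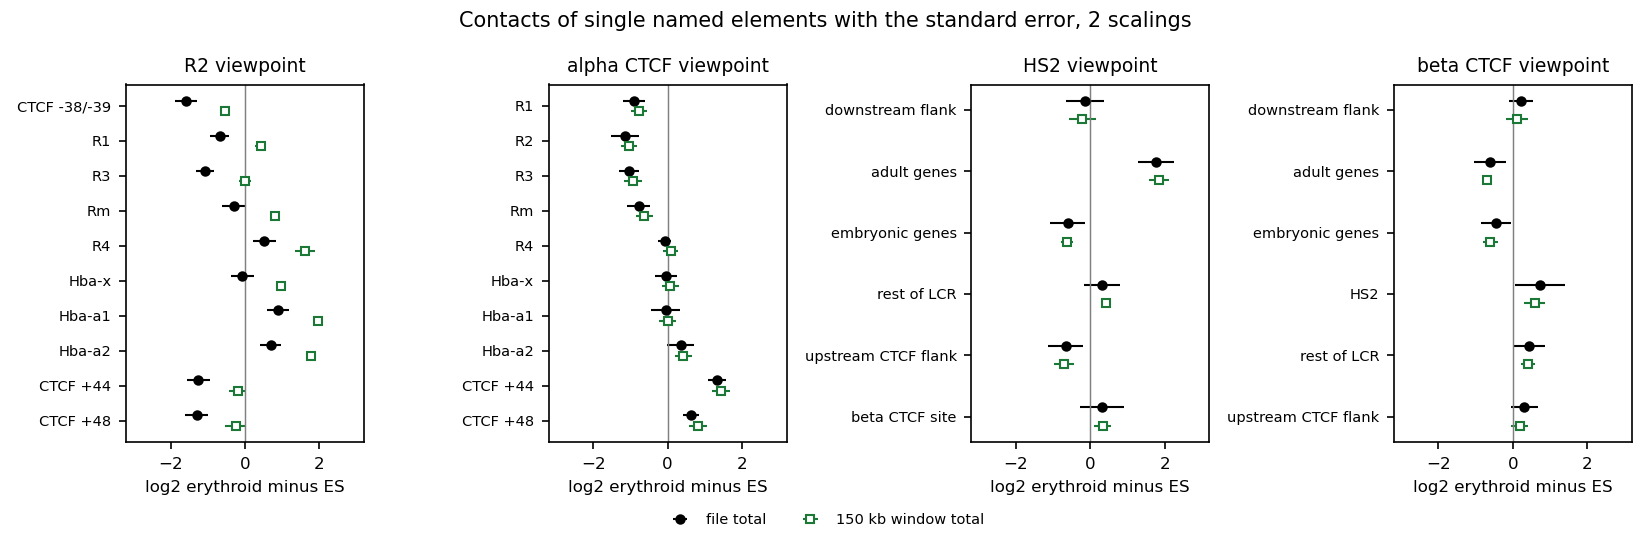
Log2 change of the contacts of single named elements, erythroid minus ES, from each viewpoint, with the standard error (n = 3 per group), relative to the table total (filled) and to the 150 kb window (open). From R2 the change at R1 goes from -0.69 to 0.42 between these scalings, while from alpha CTCF CTCF +44 stays at 1.32 and 1.44 and from HS2 the adult genes at 1.77 and 1.84.

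Over the window of alpha CTCF, 14 of 150 bins rose and 27 fell (edgeR), and DESeq2 called 27 and 18. The rises lay at +54 kb and between +62 and +92 kb, mostly beyond Hba-a2 and including bins at CTCF +44 and +48, while the bins on Hba-a2 itself were not called. The bin with the largest, of 1.52 (SE 0.21, adjusted p = 0.00152), spans 32203490 to 32205489 between Hba-a2 and +44, and the bin at CTCF +44 itself rose by 1.31 (SE 0.20). A run of falls from +8 to +20 kb held R1, R2 and R3. The other falls were mainly 50 to 148 kb upstream, with the largest, of 1.93 (SE 0.34), at 32005490 to 32007489. Groups did not overlap in 48.7% of bins, where chance gives 10%. Scaling moved the balance to 18 rises and 18 falls relative to the window and 29 and 18 with TMM, with median changes of -0.39, -0.24 and -0.10 in the order table total, window and TMM. The count of calls was 15 without erythroid replicate 1, 20 without ES replicate 1, 26 without ES replicate 2 and 21 with the first technical replicates alone.

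No pair of named elements differed past the threshold in three-way contacts with alpha CTCF: edgeR called 0 of 45, with 6 at unadjusted p under 0.05, and DESeq2 0. R1 with R2 and R2 with R3, pairs of neighbouring enhancers, had the changes -1.70 (SE 0.58) and -2.02 (SE 0.62), and both passed the threshold relative to the window (-1.73 and -1.98). Without erythroid replicate 3 edgeR called 3 pairs and without ES replicate 2 it called 1. Against the expected count edgeR also called 0, with 1 at unadjusted p under 0.05, and DESeq2 0; in this viewpoint, too, Hba-a1 with Hba-a2 stood above the expected count, by 3.23 in erythroid and 2.92 in ES cells (5.91 and 5.17 with gene copy pairs left out of the fit), under the same limit of nearly identical copies.

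Of 1127 bin pairs seen with alpha CTCF, 14 rose and 13 fell (edgeR). Of the 5 named rises, 4 involved bins at +64 to +76 kb, between Hba-a2 and CTCF +44. Pairing these with each other gave rises of 2.79 (SE 0.72) and 2.76 (SE 0.80), and pairing them with a bin 20 kb upstream gave 3.56 (SE 1.02) and 3.13 (SE 0.88). The remaining rise joined the bins at +32 to +36 kb and +40 to +44 kb (4.50, SE 1.37). They only partly overlap the windows of R4, at 30 to 33 kb, and Hba-x, at 38 to 41 kb. Among the named falls was R1 with a bin 72 kb upstream, with 2 counts in erythroid and 86 in ES cells (-5.92, SE 1.40). Groups did not overlap in 21.8% of bin pairs, where chance gives 10%. DESeq2 called 69 pairs. These calls depended on single replicates: edgeR made 0 calls without erythroid replicate 1 or ES replicate 1, with 104 and 140 pairs at unadjusted p under 0.05, 6 without erythroid replicate 3, 7 without erythroid replicate 2 or ES replicate 3, and 14 without the erythroid first technical replicates. Where the call was lost without a replicate, the change was 2.27 to 7.91 for the named rises, and for R1 with the bin 72 kb upstream it was -5.52 without erythroid replicate 1 and -6.06 without ES replicate 1.

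The share of alpha CTCF contact pairs with both fragments within 100 kb was 25.7% ± 6.26 in erythroid and 28.0% ± 7.23 in ES cells, a difference smaller than the spread between replicates (n = 3, exact two-sided permutation p = 0.7).

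At the beta locus, HS2 contacted the adult beta-globin genes more in erythroid cells. The range of the adult genes, which encode the beta chains of adult haemoglobin, was contacted 81.1 ± 11.8 times per 1000 contact pairs in erythroid cells and 23.8 ± 9.50 times in ES cells (SD, n = 3), a log2 rise of 1.77 (SE 0.48, adjusted p = 0.00653, edgeR) that was 1.84 relative to the 150 kb window. The embryonic genes, active in primitive red cells, were at 48.7 ± 21.2 and 73.99 ± 19.2, and the rest of the locus control region, HS2's own enhancer cluster, at 92.0 ± 27.8 and 74.1 ± 30.2.

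None of the other elements passed the threshold in edgeR. The change was -0.60 (SE 0.47) at the embryonic genes, 0.31 (SE 0.47) at the rest of the control region, -0.66 (SE 0.47) at the upstream CTCF flank, -0.15 (SE 0.51) at the downstream flank and 0.32 (SE 0.60) at the beta CTCF site; relative to the chromosome total the embryonic genes and the upstream and downstream flanks turned to 0.11, 0.06 and 0.53. Relative to the window, edgeR called the embryonic genes (-0.63), the upstream flank (-0.71) and the control region (0.41), and DESeq2 called 4 elements. The call at the adult genes was lost without erythroid replicate 1 (1.79, adjusted p = 0.051) and without ES replicate 2 (1.68, adjusted p = 0.0868), against a range of 3.93e-14 to 0.151 over its 17 alternatives in edgeR and DESeq2.

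In the profile of HS2, 3 of 147 bins rose and 19 fell. All 3 rises lay in the adult gene range, at 110975846 to 110977845 (2.12, SE 0.46), 110961846 to 110963845 (1.97, SE 0.48) and 110963846 to 110965845 (2.17, SE 0.77) on chromosome 7, with adjusted p of 0.000291, 0.00138 and 0.0376 in edgeR. At the first of these, contacts went from 6.48 ± 3.01 to 28.2 ± 2.80 per 1000 contact pairs. Of the falls, 18 lay 90 to 146 kb from HS2 on the side away from the genes and 1 at -148 kb, and the largest was of 6.49 (SE 1.19), with 9 counts in erythroid and 352 in ES cells. Groups did not overlap in 38.8% of bins, where chance gives 10%. Scaling moved the balance to 12 rises and 34 falls relative to the window and to 18 and 13 relative to the chromosome total. It was 19 and 13 with TMM and 22 and 19 with DESeq2. The median change was -0.78 relative to the table total, -0.76 to the window and -0.04 to the chromosome total. With TMM it was -0.11 and with DESeq2 -0.09. The rise at 110963846 was lost without any replicate but ES replicate 1 (1.75 to 2.30). The count of calls was 7 without erythroid replicate 1 or 2, and 8 without ES replicate 2 or with the first technical replicates alone.

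**Figure D5:**
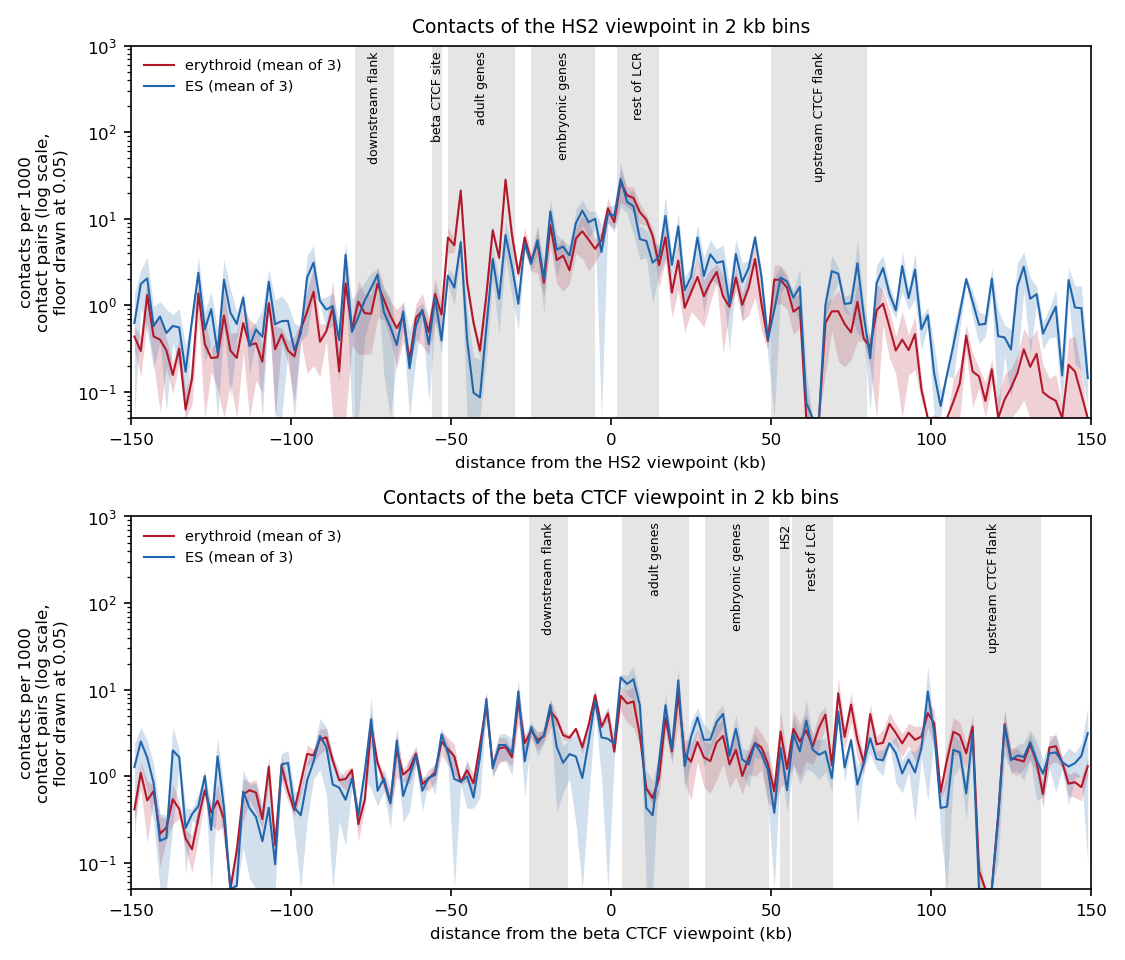
Contacts per 1000 contact pairs (log axis) in 2 kb bins against the distance in kb from HS2 (top) and beta CTCF (bottom); lines are means of 3 replicates, shading is the SD, and grey bands are the named ranges. From HS2 the erythroid line rises above the ES line in the adult gene range, where 3 bins passed the threshold, and from beta CTCF 0 of 150 bins passed it.

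The adult genes and the rest of the control region were met together with HS2 in 3.63 ± 0.54 of 1000 contact pairs in erythroid and 0.80 ± 0.58 in ES cells. The log2 change of 2.17 (SE 0.70, adjusted p = 0.0956) missed edgeR's threshold and passed it relative to the window (2.40, SE 0.64). Of the 10 element pairs edgeR called 0, with 1 at unadjusted p under 0.05, and DESeq2 called 2; without ES replicate 1 edgeR called 3. Against the expected count, adult genes with the rest of the control region stood at 0.52 in erythroid and 0.51 in ES cells, so that the difference between cell types was 0.01 (SE 0.20), and edgeR called 0 pairs, with 0 at unadjusted p under 0.05, and DESeq2 0.

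Bin pairs seen with HS2 gave 2 rises and 0 falls among 504 (edgeR). Both joined a bin of the adult gene range with the bin beside HS2 on the side of the genes. They had 521 against 7 counts (5.62, SE 1.26, adjusted p = 0.00452) and 373 against 8 counts (4.94, SE 1.32, adjusted p = 0.0465). The ES counts of each rise lay in a single replicate, and over 15 alternatives the rises were of 4.28 to 10.04 and 3.54 to 9.51. Neither passed the threshold without erythroid replicate 1 (5.56 and 4.92) or 2 (5.67 and 5.06), nor the second without ES replicate 2 (4.53) or 3 (4.42), and the count was 10 without erythroid replicate 3, 4 without ES replicate 1 and 1 without ES replicate 2 or without the erythroid first technical replicates. DESeq2 called 45 pairs. Groups did not overlap in 18.5% of pairs, where chance gives 10%. The share of HS2 contact pairs with both fragments within 100 kb was 11.9% ± 4.41 in erythroid and 11.4% ± 4.40 in ES cells (n = 3, exact two-sided permutation p = 1.0). Among pairs with both fragments on chromosome 7 it was 37.6% ± 1.95 and 21.1% ± 6.26 (n = 3, exact two-sided permutation p = 0.1, the smallest possible here).

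From the beta CTCF site no named element differed past the threshold. The adult genes were contacted 44.3 ± 18.4 times per 1000 contact pairs in erythroid and 68.3 ± 19.2 times in ES cells (SD, n = 3), a log2 change of -0.62 (SE 0.43), and at the embryonic genes it was -0.45 (SE 0.40). The HS2 enhancer was at 3.67 ± 2.34 and 2.21 ± 0.93 (0.73, SE 0.68) and the rest of the control region at 20.5 ± 9.03 and 15.2 ± 7.27 (0.43, SE 0.44). At the flanks the change was 0.22 (SE 0.33, downstream) and 0.31 (SE 0.37, upstream). edgeR called 0 of these 6 elements, with 0 at unadjusted p under 0.05, and DESeq2 called 2. Relative to the window, edgeR called the adult genes (-0.71) and the embryonic genes (-0.61), and without erythroid replicate 3 the embryonic genes alone (-0.96).

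From beta CTCF, edgeR called 0 of 150 bins, with 20 at unadjusted p under 0.05, while DESeq2 called 8 rises and 15 falls, and without ES replicate 1, the deepest of the ES replicates, edgeR called 32. Groups did not overlap in 18.7% of bins, where chance gives 10%, and the median log2 change was 0.16 relative to the table total and 0.56 to the chromosome total. edgeR called 0 of 15 element pairs, with 2 at unadjusted p under 0.05, and DESeq2 0. Against the expected count it called 0, with 0 at unadjusted p under 0.05, DESeq2 0, and 1 without ES replicate 1. Of 1398 bin pairs, 1 fell, a pair named after its values were seen: 110819489 to 110823488 with a bin at the end of the adult gene range, 110979489 to 110983488. It had 85 counts in ES replicate 3, 6 in ES replicate 1 and 0 in the other 4 replicates. That call was lost without any of the erythroid replicates, and without ES replicate 3 there were 4 others. In 15.52% of bin pairs the groups did not overlap, where chance gives 10%. The share of beta CTCF contact pairs with both fragments within 100 kb was 9.03% ± 3.75 in erythroid and 8.49% ± 3.06 in ES cells (n = 3, exact two-sided permutation p = 0.9), and among pairs with both fragments on chromosome 7 it was 24.6% ± 4.43 and 17.3% ± 5.53 (n = 3, exact two-sided permutation p = 0.3). In simulated data of this viewpoint, 5.33% of bins changed 2-fold were recovered, so changes of that size were mostly not detectable at the depth and spread of these replicates.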

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

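The tests of ligation noise, of equal fragments, of duplicates at the gene copies and all tests at the adult beta-globin genes were chosen only after the result was seen. What drew attention to the fragments in this paragraph is a high count off the viewpoint chromosome. Their contacts enter comparisons of element pairs only through the table's total count. Comparisons of single elements also count them directly where the partner fragment lies in the element. In the R2 table the most counted such fragment, listed at chromosome 2, 98507183 to 98507385, had 10159 counts, where the mean off-chromosome fragment had 4.78; it took 744 ± 122 of 100000 counts in erythroid and 345 ± 102 in ES replicates (SD, n = 3). In the alpha CTCF table it was the fragment listed at chromosome 5, 81351805 to 81352202, with 9311 counts against a mean of 4.94 (535 ± 55.8 and 554 ± 98.4 per 100000, n = 3), at 199 per 100000 in the erythroid first technical replicates and 595 in the other erythroid libraries. In the HS2 table it was listed at chromosome 10, 39356187 to 46356335, with 5878 counts against a mean of 6.60 (470 ± 55.9 and 306 ± 95.2 per 100000, n = 3). In the beta CTCF table it was listed at chromosome 9, 39356187 to 46356335, with 15148 counts against a mean of 9.25 (461 ± 65.4 and 326 ± 95.6, n = 3). Both of these listed fragments are 7000149 bp long, against median lengths of 152 and 154 bp for fragments on the viewpoint chromosome in the HS2 and beta CTCF tables, so these 2 counts cannot be compared with the mean per fragment. Since the listed off-chromosome coordinates follow the fragment boundaries of the viewpoint chromosome, none of these was read as a place in the genome.

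Off-chromosome contact pairs took a larger share of the R2 table in erythroid than in ES replicates. Ligation noise of the whole library would raise the share at every viewpoint; the differences of 18.35 (SE 6.28) at HS2 and 12.49 (SE 7.41) at beta CTCF go with that, but the difference at alpha CTCF of -2.07 percentage points (SE 4.62) argues against noise common to all viewpoints. Residual duplicates are argued against by the difference at R2 with each fragment pair counted once per library, 30.89 percentage points (SE 4.12). Noise that differs between viewpoints, a difference between the cell types at R2, and one between the strains stay open and were not tested; cell type and strain cannot be separated, because each cell type came from its own strain.

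Hba-a1 and Hba-a2 occurred together in ES contacts of R2 far above the expected count. Reads of one copy assigned to the other were first tested by laying both copies over each other, which gave 1.35 times the expected share (SD 0.03, n = 3); that test was void, because the ratio cannot exceed 1.40 or 1.41 in ES replicates 1 and 3. In a later test, contact pairs that join a fragment and its equal in the other copy were 3.61 times as frequent as their separate counts give (SD 1.15, n = 3), a value that this explanation needs. Residual duplicates are argued against by a log2 value of 2.82 with each fragment pair counted once (adjusted p = 1.2e-64, edgeR). Contact between both genes on one allele stays open and was not tested.

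The adult beta-globin genes were contacted more from HS2 in erythroid than in ES replicates. Strain sequence that maps poorly at the adult genes would lower them in ES cells from beta CTCF as well, where the log2 difference was -0.62 (SE 0.43), which argues against it. Residual duplicates are argued against by 1.34 (SE 0.33) with each fragment pair counted once, and an effect of the erythroid first technical replicates, which stood apart in counts per fragment pair, by 1.74 (SE 0.48) without those libraries. A difference between the cell types stays a hypothesis, found and tested on the same data, and a strain difference of another kind stays open.

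The 6 replicates can be divided into groups of 3 in 10 ways, too few for a share under 0.05. For R2 the real division gave 137 bins, 274 bin pairs, 4 element pairs and 2 element pairs against the expected count, with 0 as the highest other for each, and 1 of the 10 reached each real value. For alpha CTCF it gave 41 bins and 27 bin pairs (highest other 0, reached by 1 of the 10) and 0 element pairs in both tests (highest other 0, reached by 10). For HS2 it gave 22 bins (highest other 0) and 2 bin pairs (highest other 1), each reached by 1, and 0 element pairs in both tests (highest other 1, reached by 10). For beta CTCF it gave 0 bins (highest other 0) and 0 element pairs in both tests (highest other 1), each reached by 10, and 1 bin pair (highest other 1), reached by 4.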

How the results depend on the processing

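Counting each fragment pair once per library, the chromosome total as library size or as the base of the share within 100 kb, the fits without the erythroid first technical replicates, DESeq2 with the file total or the expected count as size factor, the fit without gene copies and all tests of single elements were chosen only after the result was seen. The difference in the share of contact pairs within 100 kb from R2, -15.98 percentage points, was -18.63 to -10.76 when a replicate was left out and -8.99 with each fragment pair counted once, but turned to 3.68 as a share of the pairs with both fragments on the viewpoint chromosome. On that base it was -2.99 for alpha CTCF, 16.4 for HS2 and 7.33 for beta CTCF; the cause was not tested. From the other viewpoints it had no steady sign, with -5.67 to 1.82 for alpha CTCF, -1.93 to 2.29 for HS2 and -1.59 to 1.95 for beta CTCF when a replicate was left out. Where counts moved, the cause was not tested, except that fewer bins, libraries or counts lower the number of tests or their power by construction. In simulated data with the real depth and spread, few 4-fold changes of bin pairs were recovered from HS2 and beta CTCF; depth and the spread between replicates were not separated.

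Among named results, 136 of 170 comparisons of single elements from R2 kept direction and side of the threshold, 137 of 170 from alpha CTCF, 91 of 102 from HS2 and 95 of 102 from beta CTCF. For named bins these were 149 of 157, 146 of 160 and 109 of 128, and for named bin pairs 129 of 144, 69 of 145 and 18 of 30, for R2, alpha CTCF and HS2. For element pairs they were 116 of 153, 26 of 34 and 10 of 17, and against the expected count 135 of 144, 32 of 32 and 15 of 15. Among results that passed the threshold as reported or under the alternative, only single elements from R2 turned direction. Relative to the window, R1 turned to 0.42, Rm to 0.80 and Hba-x to 0.96. Relative to the chromosome total, R1 turned to 0.44, R3 to 0.034, Rm to 0.82 and Hba-x to 1.00. Both totals hold only pairs with both fragments inside, while element counts also include fragments whose partner lies outside. A turn as small as that of R3 can therefore not be read as a reversal. In DESeq2, Rm turned to 0.23 and Hba-x to 0.41; the cause was not tested.

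From R2, the 137 called bins became 66 with TMM normalization factors and 66 in DESeq2 with its own size factors, 258 with bins of 0.5 times the size and 70 with bins of 2 times the size, where 296 and 76 bins were tested. The 274 bin pairs became 107 with TMM, 178 in DESeq2, 123 with the window total, 132 with the chromosome total and 119 with the first technical replicates only; leaving out a replicate gave 120 to 257. The 4 element pairs became 8 in DESeq2 with its own size factors and 8 with the file total, 7 with the window total, 17 with the chromosome total, 12 with wider element windows, 13 with each fragment pair counted once and 1 with the first technical replicates only; without a replicate 3 to 8. The 2 element pairs against the expected count became 4 with wider windows, 4 with each fragment pair counted once, 1 with the first technical replicates only and 1 with pairs joining both gene copies left out; without a replicate 1 to 3. The 7 single elements became 4 to 6 without a replicate, and 7 without the erythroid first technical replicates.

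From alpha CTCF, the 41 bins became 21 with the first technical replicates only and 15 to 46 without a replicate. The 27 bin pairs became 57 with TMM, 69 in DESeq2, 1 with no minimum count, 0 with bins of 0.5 times the size, 16 with 5 kb around the viewpoint left out, 7 with the first technical replicates only and 78 with each fragment pair counted once; without a replicate 0 to 38. The 0 element pairs became 2 with the window total, 2 with the chromosome total and 1 with wider windows; without a replicate 0 to 3. The 0 element pairs against the expected count became 1 with each fragment pair counted once. The 5 single elements became 1 to 7 without a replicate.

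From HS2, the 22 bins became 41 in DESeq2, 46 with the window total, 12 with bins of 0.5 times the size and 8 with the first technical replicates only; without a replicate 7 to 28. The 2 bin pairs became 26 with TMM, 45 in DESeq2, 25 with the window total, 19 with the chromosome total, 19 with each fragment pair counted once, 1 with no minimum count, 1 with bins of 0.5 times the size, 0 with 5 kb around the viewpoint left out, 0 with the first technical replicates only and 1 without the erythroid first technical replicates; without a replicate 0 to 10. The 0 element pairs became 2 in DESeq2 with its own size factors, and 1 each in DESeq2 with the file total, with the window total, with the chromosome total, with 5 kb left out and with each fragment pair counted once; without a replicate 0 to 3. The 0 element pairs against the expected count became 4 with each fragment pair counted once. The 1 single element became 4 in DESeq2, 4 with the window total and 3 with the chromosome total; without a replicate 0 to 1.

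From beta CTCF, the 0 bins became 23 in DESeq2 and 1 with the chromosome total; without a replicate 0 to 32. The 1 bin pair became 3 with TMM, 3 with the window total, 2 with the chromosome total, 0 with the first technical replicates only and 0 with each fragment pair counted once; without a replicate 0 to 4. Without a replicate, 0 to 1 element pairs were called against the expected count. The 0 single elements became 2 in DESeq2, 2 with the window total and 2 with the chromosome total; without a replicate 0 to 1.

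Replicates of both cell types carry the same numbers, but same-numbered replicates did not deviate together: the correlation of their deviations ranged from -0.06 to 0.08 for R2, -0.24 to 0.19 for alpha CTCF, -0.16 to 0.03 for HS2 and -0.11 to 0.19 for beta CTCF, and not every replicate correlated best with its own number. With the replicate number as a block, the count of single elements was 4 for R2, 1 for alpha CTCF and 0 for HS2, that of bins 15 for alpha CTCF and 14 for HS2, and that of bin pairs 10 for alpha CTCF, 0 for HS2 and 0 for beta CTCF. Rising bins from R2 went from 9 to 3, with 128 and 123 falls, and rising single elements from R2 went from 2 to 0. The replicate block moved no other total of calls by over 1.5 times.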

Other observations

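The tests against the expected count within a cell type used the elements fixed in advance, but the pairs named here were chosen only after the result was seen. R2 met the embryonic gene Hba-x together with Hba-a1 less often than the expected count in both cell types, by -1.78 on the log2 scale in erythroid (n = 3, adjusted p = 0.0104, edgeR) and -1.62 in ES cells (n = 3, adjusted p = 0.0252, edgeR). These values were -0.85 and -0.74 with each fragment pair counted once, and -0.69 and -0.09 with gene copy pairs left out of the fit. Hba-x with Rm, a member of the enhancer cluster, stood at -1.18 in erythroid (n = 3, adjusted p = 0.0168, edgeR) and -0.61 in ES cells; the erythroid value was -0.54 counted once and -0.32 without gene copy pairs. From beta CTCF, the adult with the embryonic beta-globin genes stood at -0.95 in erythroid cells (n = 3, adjusted p = 0.0156, edgeR), but at -0.03 counted once. In ES cells the downstream and upstream flanks stood at 1.52 with that viewpoint (n = 3, adjusted p = 0.00304, edgeR), but at 0.58 counted once (adjusted p = 0.618, edgeR).

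Within each replicate, the off-chromosome share from R2 minus that from alpha CTCF was 23.4 ± 0.710 percentage points in erythroid and -10.4 ± 0.532 in ES cells (SD, n = 3, exact two-sided permutation p = 0.1, the smallest possible here). From HS2 minus beta CTCF it was 3.14 ± 2.55 and -2.72 ± 7.29 (n = 3, exact two-sided permutation p = 0.2). In the R2 table, the fragment pairs with neither fragment on chromosome 11 were also compared between libraries, as a percent of the smaller library's distinct pairs. A median of 0.448% was shared between the erythroid first technical replicates, 0.120% between one of these and another library, 0.313% between other libraries of the same biological replicate and 0.472% between other libraries of different ones. The highest share between different biological replicates was 2.56%, against 0.699% within the same replicate. For HS2 these were 3.88% and 0.633%, and for beta CTCF 8.53% and 1.09%. What this means for the independence of the replicates was not tested.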
